A study of Drosophila melanogaster with 6 samples.

How the data were processed

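DamID was done in Drosophila larval brains with Dam alone, Dam-Simba1 or Dam-Simba2 under grh-Gal4, with 1 sample per group in each of 2 batches. Per the labels, embryos were collected over 4 h, kept at 18 °C for 44 h and moved to 29 °C for 24 h, and sequencing used paired reads of 250 bp. Per the submitters' processing notes, reads were made with bcl2fastq 2.19.0.316, checked with FastQC and aligned with Bowtie2 to dm6, and ChIPseeker was used; trimming and alignment options are not given in the sources used here. Per the file headers, the authors called peaks with MACS 3.0.0 for each fusion library against the Dam control of its batch, without pooling batches, in single-read mode, with at most 1 tag per position. The headers give tag sizes of 150, 149, 133 and 130 bp and fragment lengths of 277, 272, 279 and 279 bp (Simba1 batches 1 and 2, Simba2 batches 1 and 2). The q limit in the headers was 1, so no peak had been removed by q, and the effective genome size was 2910000000 bp, which is 21.7 times the 134 Mb of the arms 2L, 2R, 3L, 3R, 4 and X. This size lowers the genome-wide background that MACS uses as a minimum.

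The deposited pileup signal is coverage at the summit by reads extended to the fragment length, with the larger of the treatment and control scaled to the smaller, per the file headers. The deposited -log10 p and -log10 q values are those of a Poisson test of the pileup against the local background (lambda) of the Dam control, as the authors' MACS run gave them. The deposited fold enrichment is a ratio, pileup plus 1 over lambda plus 1, from the authors' MACS run. Lambda was recovered from this ratio, and the p values computed from it were checked against the deposited ones: 99.3 to 100% of peaks per library were within 0.01 on the -log10 scale. Depth is the number of tags after filtering, as the headers give it. Counts of peaks have no replicate below the library, and intervals on shares (exact Clopper-Pearson, 95%) cover counting error only.

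Peaks of every sequence were counted for the number per library, and the 6 arms were used elsewhere. Overlap of peaks by 1 bp or more was compared with 1000 circular shifts of 1 list along each arm, and positions relative to genes with 200 shifts. The p for overlap rests on the covered length shared by a pair. Genes came from the RefSeq table of the same build, with 17684 genes on the arms, 13922 of them protein coding. The table gives gene spans without strand, exons or transcription start sites, so a peak was assigned to a gene when it overlapped the span or 1000 bp beyond either end. The design had named the upstream side alone; the table could not give that side. A peak can be assigned to several genes. Exon, intron and promoter positions, GATC sites, and the Simba1 and Simba2 loci, which had no match by these symbols, were not analysed here.

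Samples were grouped by the labels, and the 2 libraries per protein were compared by exact two-sided permutation. The batch pairs Simba1 and Simba2 libraries through their shared Dam control. This pairing was checked in 13384 bins of 10 kb: the deviation of each library from the mean of its protein correlated between Simba1 and Simba2 (Pearson r = 0.220, across bins, which are not independent replicates). Within-batch values and a block value are therefore given beside the means. Reads were not used here, so the effect of the shared control could not be simulated or removed by splitting it; only pairs from different batches have separate controls.

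The 18 gene lists, most of the tests, the first set of alternatives and the rule for named genes were written before the data were examined. For sets of genes the plan named a comparison with independent sets alone. Span-matched draws for these sets, and binomial tests against the share at genes of like span, were not planned. Of the list symbols, 488 matched a gene and 1 (PtpMeg2) did not; Dl and Tor are listed in the table as Delta and mTor, and phl as Raf. Each list's count of genes with a peak in both batches was compared with 100000 random lists matched on 10 classes of gene span (two-sided permutation, Benjamini-Hochberg over 36 tests). Genes within a list were treated as exchangeable, which neighbouring genes with a common peak are not. Differences between proteins used exact McNemar tests on genes with a peak of 1 protein (Benjamini-Hochberg over 18 lists in 2 batches). Sets of genes with peaks in both proteins were compared with draws matched on span. A test of other splits of the samples needs at least 3 samples per group, and a test for outlying samples at least 4, so neither was done.

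Named genes were grh; every Wg/Wnt gene with a peak in all 4 libraries, in full for the 10 with the highest mean percentile of the best peak's -log10 q within its list; the 8 highest genes per protein; the 6 highest genes with peaks in both batches of 1 protein and neither of the other; and up to 4 genes per other list. This gave 107 genes, of which 79 had a peak with q of 0.05 or lower in all 4 libraries. Any other gene or region named was chosen after its values were seen.

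Alternatives were a q of 0.001 or 0.05, equal list lengths (16837 peaks), a q of 0.05 with lambda also held at or above the arm average (q of 0.05 and the fly genome size together), 50% reciprocal overlap, random placement, merging within 500 bp, arms alone, gene spans without flanks, other nulls and backgrounds for the lists, and leaving out libraries. The code was tested on simulated data: with 0, 20 and 50% of 16837 peaks kept in place it returned -0.0410, 20.4 and 50.0%. In 400 simulated lists matched to the Wg/Wnt list in size and span, peaks were planted at genes without them for 0, 10, 20 or 30 percentage points, as far as such genes were left. For Simba1 the mean share with peaks was then 59.7, 69.9, 78.5 and 90.7%, and an unadjusted p under 0.05 was found in 3, 16, 59.0 and 97.5% of lists. For Simba2 the shares were 79.4, 88.1, 96.6 and 99.9%, and such a p was found in 2, 28.5, 83.8 and 99.8%. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.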

Results

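Simba1 and Simba2, a pair of Drosophila microproteins, were each fused to the bacterial adenine methylase Dam and expressed in larval brain neural stem cells (NSCs) from the grh-Gal4 driver. In this method, DamID, DNA near the fused protein gains methyl groups on GATC sequences, and methylated DNA is enriched and sequenced. The 6 samples form 3 groups of 2 (Dam alone, Dam-Simba1 and Dam-Simba2), with 1 sample of each group in each of 2 batches. Peak lists of the 4 fusion libraries were used, each called by the submitters against the Dam control of its own batch, so the control enters every value as the background. After removal of duplicates the fusion libraries held 1191497 (Simba1 batch 1), 1506081 (Simba1 batch 2), 1069703 (Simba2 batch 1) and 1267661 reads (Simba2 batch 2). The Dam controls held 868080 (batch 1) and 1321104 reads (batch 2). Each group had 2 libraries, so the smallest p an exact two-sided permutation test of Simba1 against Simba2 can give is 0.333, and such p-values measure only the spread between these libraries. Fold enrichments and q values are the authors' (MACS), and serve only to describe or rank peaks within their own list.

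The first comparison asked how many regions each fusion protein marked above Dam alone. Simba2 libraries had more peaks than Simba1 libraries in both batches, with 22479 against 17254 in batch 1 and 35237 against 21026 in batch 2. The means were 28858 ± 9021 peaks for Simba2 and 19140 ± 2667 for Simba1 (SD, n = 2; exact permutation p = 0.333, two-sided). The ratio of Simba2 to Simba1 was 1.30 in batch 1 and 1.68 in batch 2, and 1.48 as the geometric mean of the batches. Peaks covered 6.16% (Simba1 batch 1), 6.58% (Simba1 batch 2), 7.88% (Simba2 batch 1) and 12.4% (Simba2 batch 2) of the 6 chromosome arms, with median lengths of 380 to 425 bp. The lists had been written without a q limit: 60.4% of peaks (95% exact Clopper-Pearson interval 59.7 to 61.2) had a q of 0.05 or lower in Simba1 batch 1 and 42.4% (41.8 to 43.1) in Simba1 batch 2. For Simba2 these shares were 52.7% (52.0 to 53.3) in batch 1 and 56.1% (55.6 to 56.7) in batch 2, where all intervals cover counting error only. At a q of 0.001 or lower, 4055 and 1961 peaks remained for Simba1 and 4749 and 8446 for Simba2 (batches 1 and 2).

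**Figure D1:**
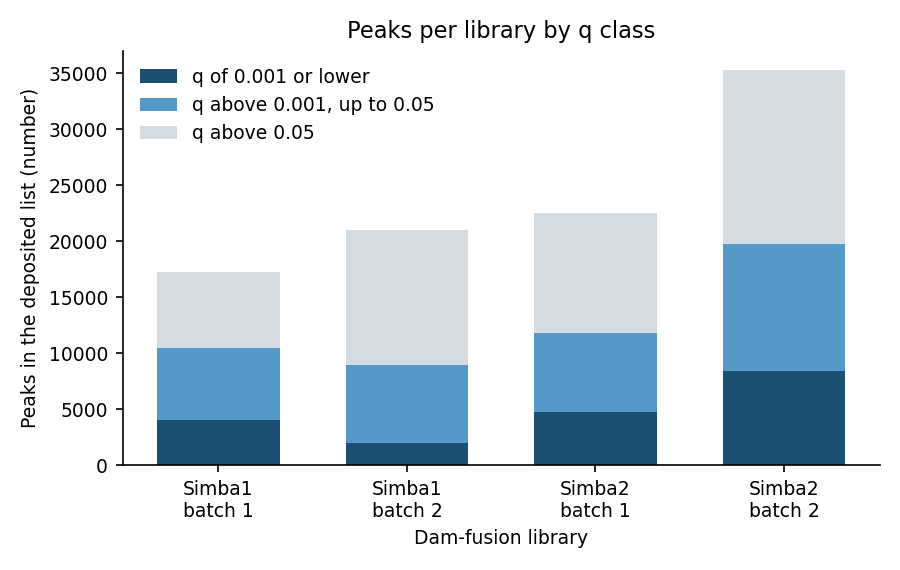
Number of peaks (y axis) in each of the 4 fusion libraries (x axis), as bars stacked by q class: 0.001 or lower, above 0.001 up to 0.05, and above 0.05. Simba2 batch 2 has the most peaks in all (35237), with q of 0.05 or lower (19785) and with q of 0.001 or lower (8446), and Simba1 batch 2 the fewest at q of 0.001 or lower (1961).

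The next comparison asked whether the same regions were marked in both batches and by both proteins. The region with the highest mean rank among those in all 4 lists lay in smog, which encodes a G protein-coupled receptor (2L, 4855564 to 4857393), and the next in grh, a transcription factor gene expressed in NSCs (2R, 17831828 to 17832411). Such regions were few: of 55460 merged regions, 58.3% were in a single list and 2492 (4.49%) were in all 4. At q of 0.001 or lower, 79 of 13894 regions were in all 4 lists. Between batches of 1 protein, 26.9% of Simba1 batch 1 peaks overlapped a Simba1 batch 2 peak, against 13.6% for peaks shifted along the arms (ratio 1.98). For Simba2, 51.9% of batch 1 peaks overlapped a batch 2 peak, against 23.5% after shifting (ratio 2.21). Between proteins, the 2 libraries of batch 1 overlapped most, with 65.6% of Simba1 peaks at a Simba2 peak against 15.5% after shifting (ratio 4.23). The Simba1 and Simba2 libraries of batch 2 gave 44.0% against 22.6% (ratio 1.94). Across batches, where the Dam controls were separate, Simba1 batch 1 and Simba2 batch 2 gave a ratio of 2.30, and the other such pair, Simba1 batch 2 and Simba2 batch 1, 1.90. With lists of equal length these ratios were 2.72 and 1.93, against 1.97 for the Simba1 batches and 2.74 for the Simba2 batches. The covered length of every pair exceeded all 1000 shifts (one-sided permutation p = 0.001, the smallest they can give), which compares positions within these libraries and not conditions. The shifts did not hold peaks at GATC sequences, where the method gives its signal. An excess over them could therefore arise without common targets, and how much was not tested. Ranks by peak score were weakly related between batches: Spearman's rho over shared peaks was 0.0916 for Simba1 (4528 peaks) and 0.238 for Simba2 (11281 peaks). Between Simba1 and Simba2 within a batch, rho was 0.412 in batch 1 and 0.186 in batch 2. These are correlations across peaks, and peaks are not independent replicates.

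**Figure D2:**
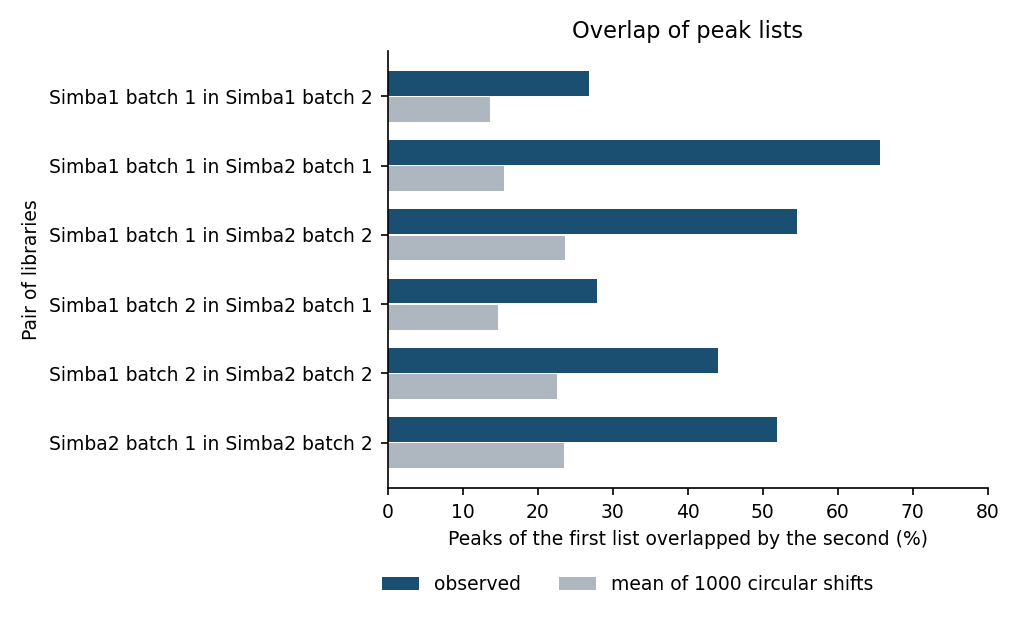
Share of peaks of the first library that overlap a peak of the second (percent), for each of the 6 pairs of fusion libraries, beside the mean share after circular shifts along the arms. The batch 1 pair of Simba1 and Simba2 stands highest (65.6% against 15.5%), and the pair of Simba1 batches lowest (26.9% against 13.6%).

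Genomic position was compared to ask where peaks of each protein lie relative to genes. Gene spans held 71.9% and 67.4% of Simba1 peaks (batches 1 and 2) and 72.4% and 74.2% of Simba2 peaks, against means of 72.2 to 72.5% for shifted peaks. Both batch 1 shares lay within the range of the 200 shifts. Simba1 batch 2 lay below all of them (lowest 70.9%) and Simba2 batch 2 above all (highest 73.3%). Regions within 1 kb of a gene end, which take in promoters, held 35.0% of peaks in Simba1 batch 1, 34.2% in Simba2 batch 1 and 36.9% in Simba2 batch 2, each above all 200 shifts (highest 33.3%, 33.2% and 32.9%). In Simba1 batch 2 the share was 27.9%, below all 200 shifts (lowest 30.0%). Gene ends thus held 31.4% ± 5.03 of Simba1 and 35.5% ± 1.92 of Simba2 peaks (SD, n = 2; exact permutation p = 0.667, two-sided). The difference, Simba2 minus Simba1, was -0.820 percentage points in batch 1 and 9.01 in batch 2. The batch 1 difference was positive at q of 0.001 or lower (0.745), with equal list lengths (0.493) and at q of 0.05 or lower (0.291), negative with lambda raised to the arm average on top of that q (-0.477), and batch 2 was positive in each. For gene spans the difference was 3.65 points (exact permutation p = 0.333, two-sided, n = 2), with 0.522 in batch 1 and 6.79 in batch 2. Chromosome 4 carried 1.62 and 1.47 times the mean peak density of the arms in batch 1 (Simba1, Simba2), and 0.935 and 1.17 times in batch 2.

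Genes were then asked for that each protein marked in both batches. Among the strongest for Simba1 were InR, which encodes the insulin receptor (best peaks 6.85- and 7.28-fold in batches 1 and 2), bru1, an RNA-binding protein gene (6.12- and 4.93-fold), and grh (5.72- and 4.65-fold), each with a peak in the Simba2 libraries too. The best InR peaks lay apart (3R, 21596503 to 21597458 in batch 1 and 21605877 to 21607564 in batch 2), while those of bru1 and of grh shared bases. Among the strongest for Simba2 were smog (6.53- and 8.06-fold) and Moe, the moesin gene (3.98- and 3.25-fold), also with peaks in both Simba1 libraries. The other top genes of Simba1 by mean rank were Mid1, dpr8, CG30015, Ptth and Pzl, and those of Simba2 were Ipk2, Ptth, cold, lobo, Scgalpha and wol. This rank takes the best peak of a gene and was not matched on span. Pzl held 59 to 191 peaks per library, dpr8 16 to 31 and bru1 16 to 29, while Ptth held 1 to 3. Best peaks of both batches shared bases at 2 of the 8 top Simba1 genes (bru1 and grh) and at 7 of the 8 top Simba2 genes (all but lobo). Ipk2 and cold share 1 peak (2L, 574235 to 574898), as do Scgalpha and wol, and Ptth shares its best peaks with its neighbours. A peak within the gene span or 1 kb of it was present in both batches at 5091 genes for Simba1 (28.8% of 17684 genes) and at 9068 genes for Simba2 (51.3%). Random sets matched on gene span and on the number of genes per library would share 4807 genes between batches for Simba1 (ratio 1.06) and 8440.4 for Simba2 (ratio 1.07; two-sided permutation p = 2e-05 for each, the smallest 100000 draws can give). All 4 libraries had a peak at 4270 genes, 3813 of them protein coding. Independent sets of this size would share 2611 genes, and sets matched on gene span would share 3381 (2.5 to 97.5 percentiles 3334 to 3429), a ratio of 1.26 (two-sided permutation p = 2e-05, the smallest 100000 draws can give). The span-matched draws for these sets were not planned. They leave out the Dam controls, which Simba1 and Simba2 share, so the p does not separate common targets from the common controls. Long genes collected peaks in both proteins: of 10 classes by span, the shortest had Simba1 peaks in both batches at 11.2% of genes and the longest at 87.4%, and for Simba2 these shares were 28.9% and 95.8%. The count in all 4 libraries fell to 425 genes at q of 0.001 or lower, and without Simba1 batch 2 the other 3 libraries shared 7024 genes.

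Some genes had peaks in both batches of 1 protein and none of the other. For Simba1 there were 105, headed by lncRNA:CR45284 (2L, 14032006 to 14038306; 2.77- and 4.81-fold), the mucin-related gene Mur11Da (4.40- and 4.37-fold) and Obp51a, an odorant-binding protein gene (3.08- and 3.48-fold). CG45154, CR32011 and Mur29B completed the 6 highest. Best peaks of both batches shared bases at CG45154 and at Obp51a, where they lay beyond the gene span and also reached hbs and lncRNA:CR45256. At lncRNA:CR45284, Mur11Da, CR32011 and Mur29B they lay apart. For Simba2 there were 1022. Its highest were Drsl2, Drsl3 and Drsl4, genes related to the antifungal peptide gene Drs, which share 1 peak on 3L (4.96- and 4.77-fold). Ror, which encodes a receptor tyrosine kinase, followed with 2.70- and 2.76-fold peaks on 2L that also reached bsk, and then CG8460 and asRNA:CR44116, which share their peaks. Best peaks of both Simba2 batches shared bases at Ror but lay apart at CG8460 and asRNA:CR44116. With lists of equal length the counts were 263 for Simba1 and 627 for Simba2. No expected count was computed for either set, at full or equal lengths, so these counts do not show targets of 1 protein alone. Absence of a listed peak does not show absence of binding.

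The title of the series names Wingless (Wg) signalling, and peaks at its genes were compared with those at other genes of like length. Of 32 Wg/Wnt genes, 17 had a peak in all 4 libraries. The span-matched tests cover peaks in both batches of each protein, not the counts in all 4 libraries given here. Long genes had many peaks from which the best was taken: fz and fz2 held 9 to 27 per library. The genes for the Wg receptors fz (3L, 14274343 to 14368639) and fz2 (3L, 19140975 to 19235373), the heparan sulfate proteoglycans dally (3L, 8827505 to 8891192) and dlp (3L, 14632601 to 14671609), and the pathway inhibitor nkd (3L, 19003741 to 19045449) had a peak with q of 0.001 or lower in each library. The best peaks of fz were 4.45- and 3.09-fold in Simba1 and 7.96- and 3.74-fold in Simba2 (batches 1 and 2), and those of fz2 were 4.70- and 3.83-fold and 3.91- and 4.27-fold. For dally they were 4.28- and 3.67-fold in Simba1 and 2.76- and 3.81-fold in Simba2, and for dlp 3.98- and 4.72-fold and 5.27- and 4.76-fold. For nkd they were 3.47- and 4.09-fold and 4.09- and 3.05-fold, with a best peak that also reached SmydA-2 in at least 1 library. Peaks with q of 0.05 or lower in each library were also found at pan, the gene of the pathway's transcription factor TCF (4, 69326 to 114270; 3.66- and 2.76-fold, then 6.84- and 3.01-fold), and at arm, the beta-catenin gene (X, 1891401 to 1900646; 2.40- and 4.41-fold, then 5.03- and 4.68-fold). At arm the best peaks of all 4 libraries shared the bases 1891223 to 1891480, at 1 end of the gene and next to mRpL16; at the rest of these 17 genes the best peaks did not all share bases. Merged regions with a peak of all 4 lists, whether or not the best one, lay at 8 of the 32 genes (dally, fz, pan, Apc, dlp, fz2, gro and arm). The co-receptor gene arr (2R, 13453640 to 13483229; 3.70- and 5.44-fold, then 3.12- and 4.27-fold) and the kinase genes sgg (X, 2633952 to 2679553; 4.14- and 3.35-fold, then 7.84- and 3.35-fold) and gish (3R, 16272452 to 16304768; 3.41- and 3.16-fold, then 3.27- and 3.37-fold) completed the 10 highest. Apc, Wnt4, Axn, Notum, Wnt6, gro and pygo also had a peak in all 4 libraries, none of them with q of 0.05 or lower in each. The ligand gene wg itself (2L, 7307159 to 7316265) had 0 and 1 peaks in Simba1 and 3 and 1 in Simba2, none with q of 0.05 or lower.

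As a group, Wg/Wnt genes passed no test for more or fewer peaks than genes of like span. Simba1 peaks in both batches were at 18 of the 32 genes, against 19.2 in span-matched random lists (two-sided permutation p = 0.769, adjusted p = 1). Simba2 peaks were at 28 of 32, against 25.4 (two-sided permutation p = 0.299, adjusted p = 0.896). Without matching on span, Fisher's exact test gave ratios of 1.95 for Simba1 (adjusted p = 0.00521) and 1.71 for Simba2 (adjusted p = 0.000271), so these calls ended with the matching. For Simba1 the ratio was 0.939 with all listed peaks and 1.70 at q of 0.001 or lower (two-sided permutation p = 0.187), with 7 genes. In simulated lists matched to this one in size and span, a mean share with peaks raised from 59.7% to 78.5% for Simba1 gave an unadjusted p under 0.05 in 59.0% of lists, and from 79.4% to 96.6% for Simba2 in 83.8%.

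**Figure D3:**
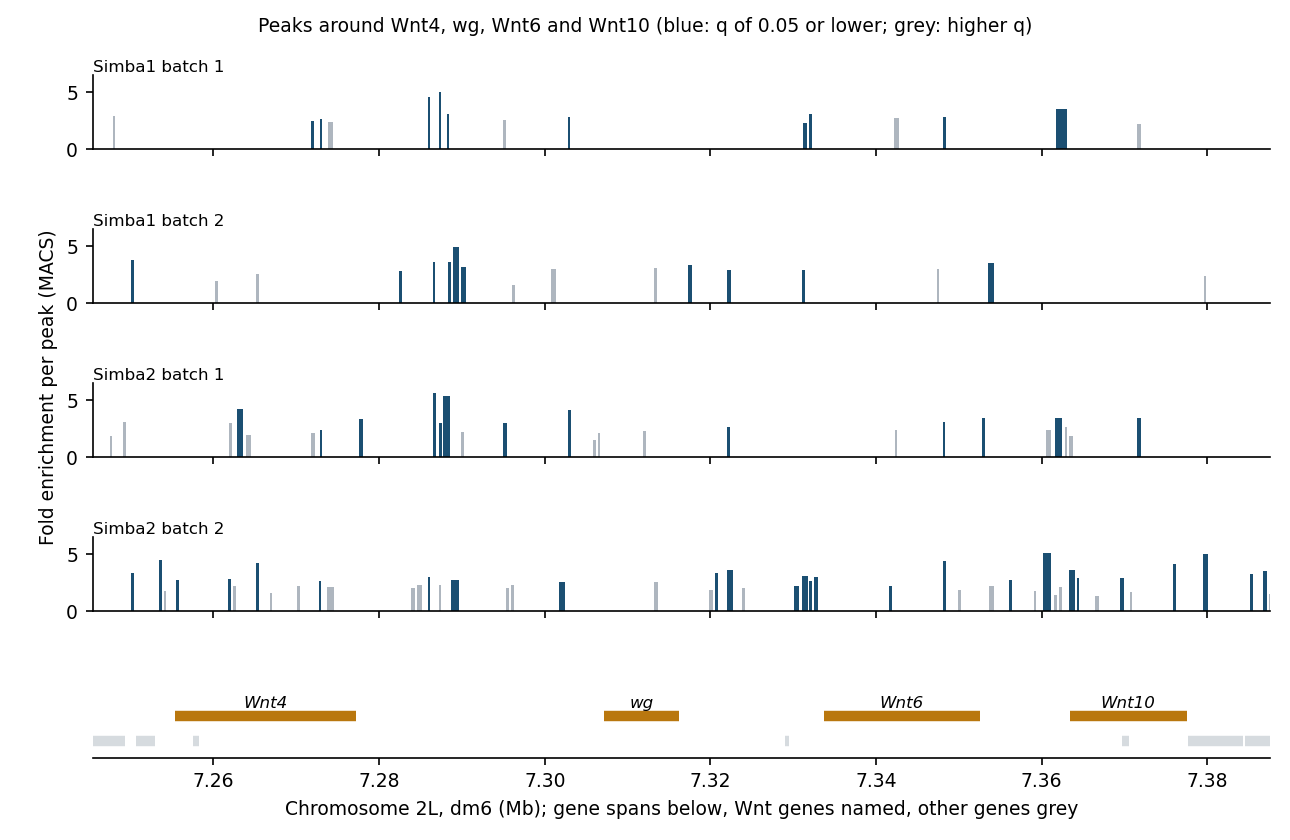
Peaks of the 4 fusion libraries in the Wnt gene cluster on 2L (7245419 to 7387528, position in the genome on the x axis), drawn at their true width and with the authors' fold enrichment as height (blue, q of 0.05 or lower; grey, higher), above the spans of Wnt4, wg, Wnt6 and Wnt10. The region holds 15 and 17 Simba1 peaks and 27 and 47 Simba2 peaks (batches 1 and 2), and wg none with q of 0.05 or lower.

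The other 17 gene lists covered signalling pathways, NSC functions, neurons, glia, muscle and control groups. NSC temporal factors had Simba1 peaks in both batches at 13 of 14 genes, against 9.68 matched (two-sided permutation p = 0.0373, adjusted p = 0.336), and Simba2 peaks at all 14 against 11.9. Among them nub had best peaks of 4.44- and 5.01-fold in Simba1 and 4.92- and 6.45-fold in Simba2, and Syp, an RNA-binding protein gene of late NSCs, 6.25- and 3.54-fold and 3.57- and 4.68-fold. At nub and at Syp the best peaks of the 4 libraries lay apart from each other. Insulin/PI3K/TOR genes had Simba1 peaks at 13 of 25 (10.8 matched) and Simba2 peaks at 21 of 25 (16.2 matched; two-sided permutation p = 0.0351, adjusted p = 0.336), among them InR, foxo and mTor with q of 0.05 or lower in all 4 libraries. Ribosomal protein genes had Simba1 peaks at 13 of 92 (16.8 matched) and Simba2 peaks at 50 of 92 (38.3 matched; two-sided permutation p = 0.0172, adjusted p = 0.321). Odorant and gustatory receptor genes, which act in sensory neurons, had Simba1 peaks at 34 of 120 (23.0 matched; two-sided permutation p = 0.0178, adjusted p = 0.321) and Simba2 peaks at 54 of 120 (52.9 matched). The ratio of observed to matched for this list, 1.48 for Simba1, was 1.09 at q of 0.05 or lower and 1.00 without the 1 kb flanks. For Simba2 it was 1.02, and 0.390 at q of 0.001 or lower (two-sided permutation p = 0.0170, adjusted p = 0.373). No list passed an adjusted p of 0.05 over the 36 permutation tests, 4 had an unadjusted p under 0.05, and the lowest adjusted p was 0.321. By the same permutation test, the ribosomal list of Simba2 passed when lists had equal length (43 against 25.8, adjusted p = 0.0072) and at q of 0.05 or lower (38 against 22.7, adjusted p = 0.0288), also with lambda, the local background, raised to the arm average on top of that limit (37 against 20.7, adjusted p = 0.0173). No other list passed in these settings, and at q of 0.001 or lower this list did not (13 against 8.96, permutation adjusted p = 0.965).

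NSC identity and asymmetric division genes had Simba1 peaks in both batches at 12 of 26 and Simba2 peaks at 20 of 26 (14.6 and 19.6 matched). Within this list, pros, the gene of a transcription factor that ends NSC self-renewal, had best peaks of 6.62- and 4.77-fold in Simba1 and 9.36- and 6.40-fold in Simba2, and brat 4.39- and 3.76-fold and 5.12- and 3.63-fold. At brat the best peaks of all 4 libraries lay apart. At pros those of batch 1 shared bases, and those of batch 2 lay elsewhere and apart. NSC quiescence and reactivation genes had peaks at 6 (Simba1) and 13 (Simba2) of 16, against 8.01 and 12.1, with mahj, Patronin and trol among those with a peak in all 4 libraries. Hippo genes had peaks at 7 and 12 of 15 (8.42 and 11.3 matched), among them ds and crb, and Notch genes at 7 and 12 of 19 (9.69 and 13.0), among them kuz and numb. EGFR/Ras genes had peaks at 10 and 14 of 15 (10.2 and 12.8), among them sty, the sprouty gene. Its best peaks were 5.12- and 3.31-fold in Simba1 and 7.08- and 2.77-fold in Simba2. Their q ranged from 1.1e-31 in Simba2 batch 1 to 0.00793 in Simba1 batch 2, where the best peak lay apart from the others. Hedgehog genes had peaks at 3 and 10 of 10 (5.0 and 7.25), with ci and hh in all 4 libraries, Dpp/BMP genes at 8 and 9 of 13 (7.47 and 9.93), with shn and tkv, and JAK/STAT genes at 3 and 3 of 7 (3.72 and 5.37), with Socs36E and dome. Cell cycle genes had peaks at 10 and 15 of 23 (8.27 and 14.1), with E2f1 and CycE, and Hox and segmentation genes at 12 and 16 of 23 (13.0 and 17.3), with hth and Ubx. Among markers of other cells, neuronal genes had peaks at 14 and 15 of 15 (11.9 and 13.8), with CadN and elav, glial genes at 5 and 7 of 13 (4.83 and 8.56), with Nrx-IV, and muscle genes at 6 and 9 of 10 (6.74 and 8.43), with bt and sls.

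**Figure D4:**
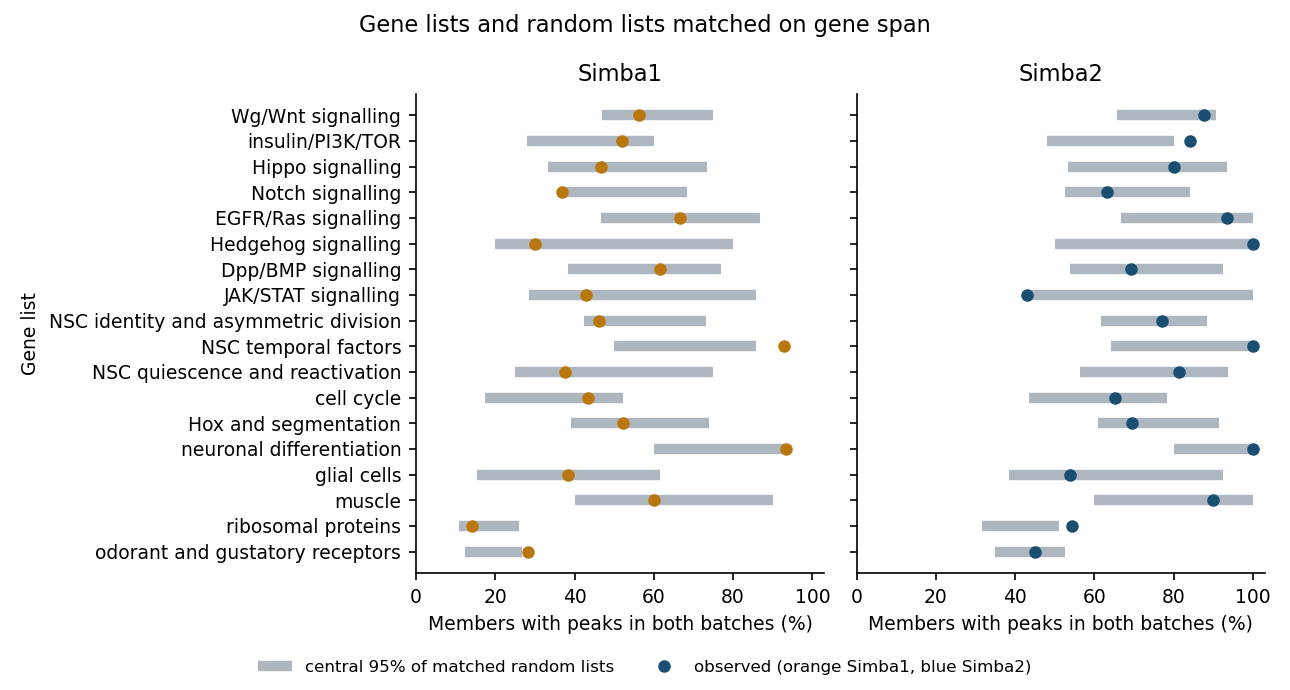
Share of genes with a peak in both batches (points, percent) in each of the 18 gene lists, for Simba1 (left) and Simba2 (right), over bars that span the central 95% of random lists matched on gene span. Wg/Wnt genes stand inside the bars, at 56.2% for Simba1 and 87.5% for Simba2, and no list passes after adjustment.

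Simba1 and Simba2 libraries were compared directly at each list, gene by gene within each batch. With 1 library per protein in a batch, these tests take genes as replicates and compare 2 peak lists of unequal length, not the proteins. Ribosomal protein genes had the lowest p in batch 2, where Simba2 had a peak at 76 of 92 and Simba1 at 23. Of these genes, 55 had a Simba2 peak alone and 2 a Simba1 peak alone (exact McNemar test, two-sided, adjusted p = 8.26e-13). In batch 1 the same list had 53 genes with a Simba2 peak and 50 with a Simba1 peak (13 and 10 alone; exact McNemar adjusted p = 1). Odorant and gustatory receptor genes had more Simba2 peaks in both batches, with 25 against 7 genes alone in batch 1 (exact adjusted p = 0.0252) and 36 against 11 in batch 2 (adjusted p = 0.00623), and NSC identity genes did so in batch 2 (9 against 0, adjusted p = 0.0352) but not in batch 1 (2 against 2). Wg/Wnt genes had a Simba2 peak alone at 3 and a Simba1 peak alone at 1 in batch 1 (exact adjusted p = 1), and at 9 and 1 in batch 2 (adjusted p = 0.0967). Against the share of Simba2 peaks at all genes of like span, which takes the longer Simba2 lists into account, no list passed in either batch (exact binomial test, two-sided, lowest adjusted p = 0.485). For ribosomal protein genes in batch 2, 38.2 genes with a Simba2 peak alone and 6.59 with a Simba1 peak alone would have been found at that share. For odorant and gustatory receptor genes these values were 19.9 and 10.2 in batch 1 and 52.1 and 7.60 in batch 2. The genes found thus lay on the Simba2 side of genes of like span in batch 1 (exact binomial test, two-sided, unadjusted p = 0.191) and on the Simba1 side in batch 2 (unadjusted p = 0.0443, adjusted p = 0.797).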

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

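The tests of pairs by list length and by control coverage were set before their results were seen; the tests of the batch difference in ribosomal protein genes and of the shared Dam control were chosen only after.

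Ribosomal protein genes with a peak of 1 protein alone were 10 for Simba1 and 13 for Simba2 in batch 1, and 2 and 55 in batch 2 (Fisher's exact test, two-sided, adjusted p = 0.000569 over 18 lists). None of the other 17 lists passed this test, which takes genes as replicates of 1 library per protein and batch and leaves out the lengths of the peak lists. Genes of like span shifted the same way, with 7.70 (Simba1) and 15.2 (Simba2) matched in batch 1 and 6.59 and 38.2 in batch 2, and against that share the ribosomal list passed in neither batch (exact binomial test, two-sided, adjusted p = 1 and 0.485), so a difference specific to ribosomal protein genes was not shown. Simba1 batch 2 had peaks at 23 of the 92 genes, and the other libraries at 50 (Simba1 batch 1), 53 (Simba2 batch 1) and 76 (Simba2 batch 2). The share of peaks within 1 kb of a gene end, Simba2 minus Simba1, was -0.820 percentage points in batch 1 and 9.01 in batch 2, a difference between batches that was not tested. The opposite signs were lost at q of 0.001 or lower (0.745 in batch 1, 15.9 in batch 2), with equal list lengths (0.493 and 13.3) and at q of 0.05 or lower (0.291 and 12.3), and present at q of 0.05 with the fly genome size, both together (-0.477 and 12.3).

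Simba1 and Simba2 peaks of batch 1 overlapped each other more than did any other pair of libraries. List length alone is argued against, since at equal lengths the batch 1 pair had a ratio of observed to shifted overlap 1.65 times that of the next pair. For low coverage of the batch 1 Dam control at the shared sites, the median lambda at shared Simba1 peaks was 1.36 times that at unshared ones. This cannot decide the question, since lambda is a local background and not the coverage at the peak itself. The ratio also did not follow the control: for Simba1 batch 1 peaks shared with batch 2 libraries, which have a separate control, it was 1.80 (Simba2) and 0.925 (Simba1). The shared Dam control alone cannot be told apart from other causes: the batch 2 pair, which also shares a control, had a ratio of 2.20 at equal lengths, inside the 1.93 to 2.74 of the 4 pairs with separate controls. Handling common to batch 1 and targets common to both proteins stay open and were not tested, and the first is confounded with the batch.

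Peaks with q of 0.05 or lower, called above the Dam control, were also present on sequences that entered no comparison beyond the number of peaks. The Y chromosome had 93 (Simba1 batch 1), 162 (Simba1 batch 2), 78 (Simba2 batch 1) and 203 such peaks (Simba2 batch 2). The mitochondrial genome had 7, 6, 4 and 4 in the same order, the ribosomal DNA unit 1, 4, 3 and 21, and other unplaced scaffolds 134, 344, 164 and 376.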

How the results depend on the processing

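Chosen after seeing the data were q of 0.05 alone or with the fly genome size, gene spans without flanks and left-out single libraries. So were the protein-coding background, 50 span classes, and all settings for list differences and peak scores. The fly genome size was run only on top of a q of 0.05, so its values compare with those at that q. Of the alternatives for the main results, 116 kept direction and call, 37 moved a value, 7 reversed a direction, and 1 gained a call with its direction kept. Of the 7 reversed, 1 also gained a call (Wg/Wnt genes of Simba1 by Fisher's exact test, adjusted p = 0.00521). For genomic positions and the ratio of peak numbers the call could not change. With so few libraries per protein, the exact permutation cannot give a p under 0.05. All 36 alternatives for the overlap of peak lists kept their call. With reciprocal overlap the call could not change, since its p rests on covered length and repeats that of the main setting. Libraries held 868080 to 1506081 reads, Dam controls included, and the median pileup of listed peaks was 8.12 to 10; the effect of depth was not tested. Except where a setting by its construction keeps fewer peaks or narrower genes, the cause was not tested.

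At q of 0.001 the mean number of peaks was 3008 for Simba1 and 6597.5 for Simba2, at q of 0.05 it was 9674.5 and 15813, and at q of 0.05 with the fly genome size 7281 and 13060. Genes with peaks in both batches were 660 (Simba1), 2715 (Simba2) and 425 (both proteins) at q of 0.001, 2604, 6103 and 2033 at q of 0.05, 2214, 5687 and 1738 at q of 0.05 with the fly genome size, and 3271 (Simba1) and 2775 (both) without flanks. With 1 library left out, genes with a peak in the other 3 numbered 4510 to 7024, highest without Simba1 batch 2.

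The paired value of the ratio of peak numbers, Simba2 to Simba1 with batch as a block, was 1.48, and 1.30 to 1.68 with 1 batch left out; mean peaks then were 17254 to 21026 for Simba1 and 22479 to 35237 for Simba2. Blocked differences in genomic position equal the differences of means. Leaving out 1 batch gave, for Simba2 minus Simba1 in percentage points, 0.522 to 6.79 in gene spans, -0.820 to 9.01 within 1 kb of a gene end, -0.474 to -0.323 within 1 kb of a gene only, and -6.31 to -0.199 elsewhere.

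Lists past an adjusted p of 0.05 were 1 with equal lengths, 1 at q of 0.05 and 1 at that q with the fly genome size, in each case ribosomal proteins for Simba2 (adjusted p = 0.0072 to 0.0288), 17 by Fisher's exact test without matching, and 0 with either batch left out. They were also 0 at q of 0.001, without flanks, with the circular shift null, with the protein-coding background and with 50 span classes (permutation, ribosomal proteins for Simba2, adjusted p = 0.965, 0.970, 0.0719, 0.378 and 0.293). Of 36 lists and proteins, 26 lay on the other side of expectation in at least 1 of 10 settings with a matched or shifted null, and the ratio moved over 1.5 times in 19. At q of 0.05 with the fly genome size, odorant and gustatory receptors had ratios of 0.942 for Simba1 and 0.542 for Simba2 (permutation p = 0.00354, adjusted p = 0.0637). The observed over expected count of Wg/Wnt genes for Simba1 was 1.70 at q of 0.001, 1.01 at q of 0.05 with the fly genome size, 1.01 without flanks, 1.95 by Fisher's exact test and 0.948 to 1.15 with 1 batch left out. For Simba2 it was 1.71 by Fisher's exact test and 0.998 to 1.14 with 1 batch left out. By Fisher's exact test 10 Simba1 and 4 Simba2 lists moved from below to above expectation, and 1 list of each protein the other way. Of these, 3 passed an adjusted p of 0.05: Wg/Wnt, EGFR/Ras (2.32) and Hox and segmentation genes (1.81) of Simba1. That test leaves out gene span, and genes matched in span to the Wg/Wnt list had Simba1 peaks in 59.9% of cases, against 28.8% of all genes.

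Lists that differed between the proteins in batch 1 were 0 at q of 0.001, 0 with equal lengths, 0 at q of 0.05, 0 at q of 0.05 with the fly genome size and 0 against the matched share. In batch 2 they were 12, 1, 10, 10 and 0. Spearman's rho across batches was 0.0416 (q of 0.001) and 0.0503 (q of 0.05 and fly genome size) for Simba1, and 0.172 (q of 0.001), 0.200 (equal lengths), 0.197 (q of 0.05) and 0.171 (q of 0.05 and fly genome size) for Simba2. Promoter definitions and promoter-only assignment were not run, as the gene table has no strand or start sites, nor was matching on GATC sites, which needs the genome sequence. Assignment by gene span is the reported setting itself.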

Other observations

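The genes, regions and gene classes here were chosen after their values were seen; the tests of gene classes and of the 6 high peaks were chosen only after, and the test of the genome size before.

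Several regions outside the named lists ranked near the top of all 4 lists. In nAChRalpha6, which encodes a nicotinic acetylcholine receptor subunit, a region on 2L (9809617 to 9811111) had peaks of 6.16- and 4.41-fold in Simba1 and 7.53- and 10.3-fold in Simba2 (batches 1 and 2). In mub, on 3L (21912227 to 21913291), the values were 4.66- and 3.61-fold in Simba1 and 6.39- and 5.68-fold in Simba2. A region on 3L that overlapped no gene span (17919454 to 17920142) had 6.90- and 6.01-fold peaks in Simba1 and 5.12- and 9.17-fold peaks in Simba2. Of the 2492 regions in all 4 lists, 1780 (71.4%) overlapped a gene span, and their median width was 783 bp. The peak with the lowest q on the arms in both batch 1 libraries lay at Ggamma30A, a G protein subunit gene on 2L (9271463 to 9273065, 15.7-fold in Simba1; 9268949 to 9273583, 19.6-fold in Simba2).

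Classes of RNA genes were compared with genes of like span in 27 permutation tests, two-sided. Genes of small nucleolar RNAs had Simba1 peaks in both batches at 9 of 269, against 30.3 matched (permutation, adjusted p = 0.00027), and Simba2 peaks at 77 against 77.9. By library their counts were 78 (88.6 matched) and 42 (75.1) for Simba1 and 100 (106 matched) and 176 (158) for Simba2 in batches 1 and 2. Genes of other noncoding RNAs had Simba2 peaks in both batches at 32 of 54, against 17.0 matched (permutation, adjusted p = 0.000432), and Simba1 peaks at 5, against 6.99 (permutation, adjusted p = 0.749). By library their counts were 26 (18.9 matched) and 14 (16.1) for Simba1 and 34 (22.5) and 45 (33.0) for Simba2. Long noncoding RNA genes had Simba1 peaks in both batches at 398 of 1959, against 357 matched (permutation, adjusted p = 0.0199), and Simba2 peaks at 728, against 752 (permutation, adjusted p = 0.539). By library their counts were 849 (799 matched) and 800 (723) for Simba1 and 967 (952 matched) and 1168 (1290.3) for Simba2, so Simba2 batch 2 lay on the other side of its matched value. Ribosomal RNA genes on the arms, which are repeated copies that share reads, had a peak at 0 of 98 in Simba1 batch 1 (32.3 matched), 1 in Simba1 batch 2 (27.4), 1 in Simba2 batch 1 (38.7) and 58 in Simba2 batch 2 (57.6), so only Simba2 batch 2 was near its matched value. Neighbouring genes can share a peak, so genes are not independent here.

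Simba1 batch 2 held 6 peaks of 81.3- to 190-fold, while the next highest in that list was 11.7-fold. They lay at Myo81F (3R, 1905909 to 1906930 and 1909363 to 1910138), at CG17698 (3L, 23736822 to 23738034), on 3L at 24579109 to 24579734, and on 2 unplaced scaffolds. At CG17698 the summit held 543 reads of the 544 that 1 tag per position allows, so its 136-fold was at the limit of the measure. Lambda of the batch 2 Dam control, recovered from fold and pileup, was below the arm average of 2.68 at all 6 sites, which raises the folds. Low control coverage alone is argued against, since the pileup was 130 to 476, against a median of 8.77 in that list. Simba2 batch 2, called against the same control, had a peak of 10-fold or more at 0 of the 6 sites. That count cannot decide the question, since the highest fold of Simba2 batch 2 at any site was 12.1. Simba1 occupancy in both batches is argued against as well, since Simba1 batch 1 had a peak with q of 0.05 or lower at 0 of them. The highest fold of any other library at these sites was 2.69. What gave these peaks, and whether any of them reflects binding, stays open.

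The effective genome size in the headers could have let weak peaks pass the q limit. With lambda held at or above the arm average, a median of 18.6% of the peaks with q of 0.05 or lower no longer met the same p limit. By library this share was 19.3% and 31.1% for Simba1 and 16.7% and 17.8% for Simba2 (batches 1 and 2). The main results use all listed peaks, for which this loss was not tested. Among all listed peaks, lambda was below the arm average at 39.96% and 52.15% for Simba1 and 40.97% and 40.39% for Simba2 (batches 1 and 2). The median of 18.6% lies between the 50% set in advance for a main cause and the 10% set for a negligible one. How far the setting shaped the lists therefore stays open. No biological explanation was tested for this.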
